A study of Homo sapiens with 4 samples.

How the data were processed

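RNA-seq was analysed for 4 libraries of the breast cancer line MDA-MB-468, 2 given DMSO and 2 given 5 µM MS1943 for 3 days, grouped by the treatment label of each sample. Per the labels' protocols, RNA was purified with a column kit and libraries were made from poly(A)-selected RNA with the TruSeq RNA Library Prep Kit v2. That kit does not mark strand, so reads of a gene and of an overlapping gene on the other strand cannot be told apart. Per the submitters' processing notes, Salmon 0.9.1, R 3.4.3 and DESeq2 were used with genome build hg38; the transcript annotation release and the Salmon options are not given in the sources used here. The estimated counts in the deposited files are Salmon's number of reads per transcript, which need not be whole, per the file headers. The TPM values in the deposited files are length-scaled transcript abundances from the same Salmon output, per the file headers, and were used only for the XBP1 transcripts. Salmon shares reads between transcripts that have sequence in common by a statistical model, so values of near-identical genes and of overlapping transcripts carry an assignment error that the files do not hold.

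Each file lists 197653 transcripts. Of these, 193505 matched GENCODE 29 by transcript identifier without its version, and the 4148 that did not match, holding 0.482% to 0.496% of the reads of each library, were left out. Copies in the pseudoautosomal region were merged. Estimated reads were summed per gene (56865 genes, 19692 of them protein coding) and rounded to whole numbers. Gene symbols were updated to current ones, and coordinates are those of GENCODE 29 on hg38, counted from 1. The libraries held 64720699 and 71378893 (DMSO) and 69878745 and 47564377 (MS1943) estimated reads. For a gene with 0 reads, the floor of 3 reads stands for 0.0456, 0.0400, 0.0451 and 0.0656 CPM in DMSO replicates 1 and 2 and MS1943 replicates 1 and 2. These floors cover counting error only, since the reads carry no molecular identifiers. The interval given for silent genes treats genes as independent.

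The test was edgeR 4.0.16's quasi-likelihood F test in R 4.3.3 with TMM scaling, filterByExpr by group and a model of treatment alone. Benjamini-Hochberg adjustment ran over 19358 tested genes, and a gene counts as changed at an adjusted p under 0.05. The common biological coefficient of variation was 0.0478. The SE of a log2 fold change is its size divided by the square root of the F statistic. The 36 gene lists cover PRC2, PRC1, genes repressed by EZH2, developmental regulators, and HOX genes. Others cover ATF4 and CHOP targets, ATF6 and XBP1 targets, heat shock, cholesterol synthesis, fatty acid synthesis, NRF2 targets, p53 targets, S phase, mitosis, interferon-stimulated genes, MHC class I, NF-kB and apoptosis. Further lists cover autophagy, lysosome, tRNA synthetases, glycolysis, hypoxia, proteasome, ribosomal proteins, and nuclear and mitochondrially encoded respiratory chain subunits. The remainder are basal, luminal and mesenchymal markers, early response genes, YAP targets, metallothioneins, and leukocyte, fibroblast and endothelial markers. Some lists share genes and so are not independent. GDF15 is on the ATF4 and p53 lists and SLC7A11 on the ATF4 and NRF2 lists. BAX, BBC3, FAS and TNFRSF10B are on the p53 and apoptosis lists. Lists with at least 5 tested members were tested with camera in limma 3.58.1 (preset correlation 0.01, log2 CPM with prior count 2). SOD2, a member of the NF-kB list, has 2 gene identifiers in the annotation and was not matched. The lists, the gene and list tests, the named-gene rule and all but the last 2 of the alternatives given below were fixed before the data were examined; the tests of the closing observations were not all, as said there.

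Named genes are, by that rule, EZH2, EZH1, EED and SUZ12; the receptor genes ESR1, PGR, ERBB2 and EGFR; the 12 largest rises and the 12 largest falls in fitted log2 fold change among changed protein-coding genes with an average log2 CPM of at least 2 and both MS1943 libraries outside the DMSO range; and, of each list, up to 4 members with the smallest adjusted p among those that passed. The opening paragraphs of the closing observations, and the few genes so marked in the results, name genes singled out after their values were seen; ATF4, XBP1 and the PTPRC reads were also added outside the rule. A few genes that the rule takes are not reported here.

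The XBP1 transcripts were classed by whether their annotated sequence holds the 26-base intron that IRE1 removes: XBP1-202 and XBP1-207 lack it. XBP1-201, XBP1-203, XBP1-204 and XBP1-206 hold it, and XBP1-205 covers neither. The gene test was tested on simulated data drawn from the means and library sizes of the real genes. With no gene changed it made 1 false call among 18905 genes. With 200 genes changed it found 43 of 65 genes changed 1.5-fold, 47 of 65 changed 2-fold and 62 of 66 changed 4-fold. It also made 13 false calls among 18915 genes. As a share of all calls made there, these 13 exceeded the adjusted p threshold. In the real data 11488 of 19358 tested genes were called, far more than the 200 simulated. The simulation therefore does not test the scaling or the error rate when that many genes change.

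The alternatives were other scalings (DESeq2-type factors, total reads), no low-count filter or 10 reads in every library, protein-coding genes only, an offset for transcript length, DESeq2 1.42.0, limma-voom, a robust edgeR fit, each library left out in turn, and, for the lists, an estimated correlation, fry and a prior count of 0.5. An analysis without the mitochondrially encoded genes, and an edgeR test with the reads of the spliced and unspliced XBP1 forms as separate rows in place of the gene, were added after seeing the data.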

Results

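Poly(A)-selected RNA was sequenced from MDA-MB-468, a human breast cancer line. The labels describe it as triple negative, meaning that it is classed as lacking the estrogen receptor, the progesterone receptor and HER2 amplification. Cells at passage 12 were given 5 µM MS1943 for 3 days (n = 2) or the vehicle DMSO (n = 2). The treatment labels give no time for DMSO. MS1943 is named in the series title as a degrader of EZH2, the catalytic subunit of Polycomb repressive complex PRC2, which methylates lysine 27 of histone H3 and is associated with gene silencing. The series' stated purpose is to profile how the compound alters the transcriptome. The deposited estimates summed to 64720699 and 71378893 reads in the DMSO libraries and to 69878745 and 47564377 reads in the MS1943 libraries. Mitochondrially encoded genes took 1.64% and 1.77% of the reads with DMSO and 3.50% and 3.09% with MS1943. The libraries of each group correlated across genes at Pearson r = 0.994 (DMSO) and 0.993 (MS1943), against 0.965 to 0.967 between groups. Both pairs differed by more than sampling noise (chi-square per degree of freedom 6.33 and 5.86), so neither pair was taken for copies of a single library. The sample titles mark each DMSO library with 1 letter and each MS1943 library with 3 letters, and no label says whether these stand for pooled dishes or for pairs. The labels describe dishes seeded in duplicate and say nothing further on whether the duplicates were independent cultures, so p-values measure the spread between these samples, which may be technical. Values below are TMM-scaled CPM, the reads of a gene scaled to a common library size, as mean ± SD of n = 2 per group, and log2 fold changes are MS1943 over DMSO ± SE.

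After 3 days of MS1943, 27 of 32 ATF4 and CHOP targets, 30 of 39 ATF6 and XBP1 targets, 20 of 23 heat shock genes and 28 of 29 interferon-stimulated genes rose, and 38 of 42 S-phase genes fell. Called as lists by camera with its preset correlation, none of these was called with an estimated correlation (adjusted p = 0.424 to 0.678). The estimated version rests on only the 2 degrees of freedom left by 4 libraries, so a lost call cannot be laid to correlation alone. HSPA1A, the inducible cytosolic HSP70, rose from 596 ± 15.6 to 5826 ± 67.8 CPM. DDIT3, which encodes the stress transcription factor CHOP, rose from 5.58 ± 0.10 to 50.4 ± 0.50 CPM, and MX1, an interferon-induced antiviral GTPase, from 45.8 ± 0.10 to 299 ± 5.81 CPM. KIF20A, a kinesin needed for cytokinesis, fell from 161 ± 0.90 to 35.9 ± 0.18 CPM. All 31 listed proteasome genes rose, immunoproteasome subunits not among them. All 39 tested G2 and mitosis genes fell, and neither list was called with an estimated correlation. On hg38, HSPA1A (ENSG00000204389) lies on chromosome 6 from 31815464 to 31817946, DDIT3 (ENSG00000175197) on chromosome 12 from 57516588 to 57521737, MX1 (ENSG00000157601) on chromosome 21 from 41420304 to 41459214, and KIF20A (ENSG00000112984) on chromosome 5 from 138178719 to 138187715. Transcripts of EZH2 itself fell slightly, by 0.19 on the log2 scale. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 11488 of 19358 tested genes passed an adjusted p of 0.05, with 5799 higher and 5689 lower. Of these, 1542 of the higher and 1535 of the lower genes changed at least 2-fold. Scaling by total reads alone shifted the median log2 fold change of all tested genes to -0.12 and the split to 4619 higher and 6973 lower (39.8% higher against 50.5%), so directions are relative to the TMM scaling.

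**Figure D1:**
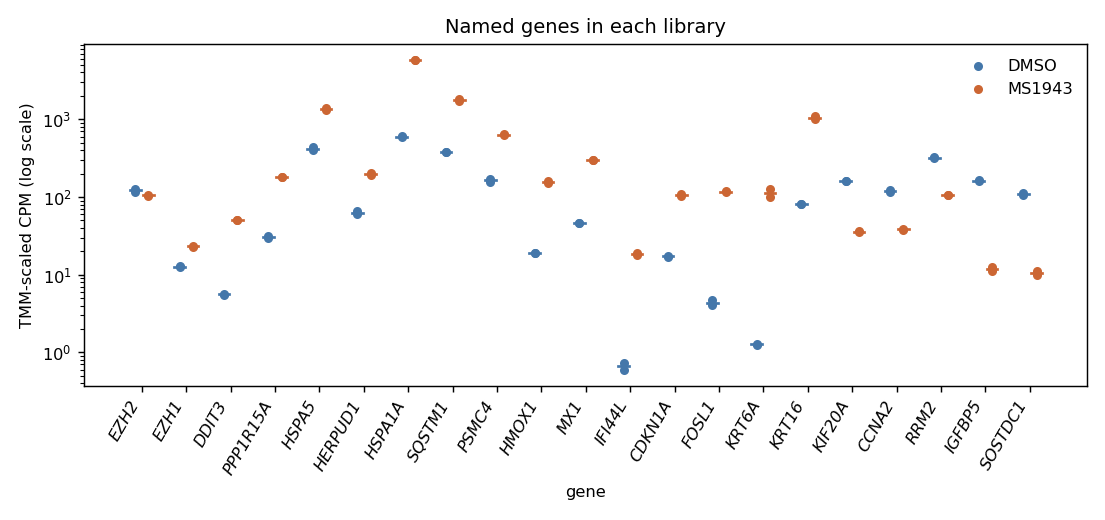
TMM-scaled CPM (log axis) of 21 named genes in each of the 4 libraries; points are libraries and short lines are group means. Blue is DMSO and orange is MS1943. HSPA1A lies at 596 CPM with DMSO and 5826 CPM with MS1943, while EZH2 lies at 121 and 106 CPM.

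The compound is described as acting on the EZH2 protein, which RNA-seq does not measure. EZH2 (ENSG00000106462, hg38 chromosome 7, 148807383 to 148884321) went from 121 ± 6.29 to 106 ± 2.25 CPM (log2 fold change -0.19 ± 0.06, edgeR adjusted p = 0.0061). SUZ12, a core PRC2 subunit, fell by a similar amount (-0.20 ± 0.06, adjusted p = 0.0080), but this call ended without DMSO replicate 1 (adjusted p = 0.0525) or without MS1943 replicate 1 (adjusted p = 0.0613). EED, the subunit that binds trimethylated lysine 27, stood at 38.7 ± 0.26 and 37.8 ± 0.78 CPM (-0.04 ± 0.06, adjusted p = 0.622) and was called lower (-0.15) only when scaled by total reads. EZH1, the paralog that can replace EZH2 in PRC2, rose from 12.6 ± 0.19 to 23.2 ± 0.55 CPM (0.88 ± 0.07, adjusted p = 2.9e-09). The PRC2 cofactor PHF1 rose from 62.4 ± 0.49 to 166 ± 3.79 CPM (1.41 ± 0.05), while EPOP (-0.999 ± 0.10) and RBBP4 (-0.53 ± 0.06) fell. Of 12 PRC2 genes, 2 rose, 8 fell and 2 did not pass. The camera test of limma did not call the list (adjusted p = 0.240). Among 17 genes of the sister complex PRC1, 4 rose and 7 fell (camera adjusted p = 0.457). PCGF1 (0.72 ± 0.07) rose, and CBX2 (-0.74 ± 0.06) and CBX7 (-0.62 ± 0.07) fell.

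Of 17 genes listed in advance as repressed by EZH2 in tumour cells, 13 could be tested, 7 rose and 5 fell, and the list was not called by camera (adjusted p = 0.556) but was by fry (adjusted p = 0.0332), which does not compare a list with the other genes. DKK1, a secreted WNT antagonist, rose from 5.54 ± 0.13 to 59.8 ± 5.94 CPM (3.43 ± 0.08, edgeR adjusted p = 6.35e-17). The transcription factor gene KLF2 rose from 1.11 ± 0.17 to 7.30 ± 1.64 CPM (2.70 ± 0.18), and the cell cycle inhibitor gene CDKN2B from 40.2 ± 1.86 to 77.2 ± 6.45 CPM (0.94 ± 0.06). TIMP3, a metalloproteinase inhibitor, fell from 207 ± 1.38 to 119 ± 1.62 CPM (-0.80 ± 0.05). Of 65 listed developmental regulators commonly bound by PRC2, only 28 could be tested, so the counts leave out most of the list. Of the 28, 2 rose and 14 fell (15 lower when adjusted over the list alone), with median log2 fold change -0.31 and camera adjusted p = 0.0223. That list call ended with an estimated correlation (adjusted p = 0.678 with an estimated correlation), with total-read scaling (adjusted p = 0.0527) and without MS1943 replicate 1 (adjusted p = 0.0610), and fry gave an adjusted p of 0.0514. WNT6 fell from 71.03 ± 9.90 to 22.7 ± 3.16 CPM. The homeobox genes IRX3 (-0.85 ± 0.06) and IRX5 (-0.89 ± 0.07) fell too. PAX8, by contrast, rose from 0.51 ± 0.01 to 4.76 ± 0.42 CPM (3.22 ± 0.18). Of 39 listed HOX cluster genes, 26 could be tested, of which 3 rose and 11 fell (camera adjusted p = 0.0566, fry 0.0132). HOXC6 rose (0.92 ± 0.11), as did HOXC13 (0.40 ± 0.07), and HOXB7 (-0.78 ± 0.11) and HOXC12 (-0.41 ± 0.07) fell.

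The receptor genes that define the line's class were read directly. PGR, the progesterone receptor gene, had 0 reads in all 4 libraries, which allows up to 0.0400 to 0.0656 CPM per library at a floor of 3 reads. ESR1, the estrogen receptor gene, was low and rose from 3.21 ± 0.05 to 4.97 ± 0.20 CPM (0.63 ± 0.13, edgeR adjusted p = 3.8e-04), a call that ended when the test allowed for changes in transcript length (0.33, adjusted p = 0.139). ERBB2, which encodes HER2, fell from 81.8 ± 0.32 to 65.0 ± 2.50 CPM (-0.33 ± 0.06, adjusted p = 3.8e-05). EGFR, the epidermal growth factor receptor gene, rose from 4376 ± 123 to 6520 ± 332 CPM (0.58 ± 0.07, adjusted p = 7.7e-07).

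Of 32 ATF4 and CHOP targets, the genes of the integrated stress response, 27 rose, 0 fell and 5 did not pass (median log2 fold change 1.19, camera adjusted p = 3.7e-11; adjusted p = 0.424 with an estimated correlation). DDIT3 rose 9.02-fold (3.17 ± 0.07, edgeR adjusted p = 3.6e-17). PPP1R15A, which encodes the phosphatase subunit GADD34, rose from 30.5 ± 1.48 to 180.2 ± 1.26 CPM. STC2, a secreted glycoprotein gene, rose from 51.8 ± 0.28 to 263 ± 3.90 CPM and the transcription factor gene ATF3 from 12.2 ± 0.09 to 68.9 ± 2.01 CPM. ATF4 transcripts stood at 947 ± 25.7 and 984 ± 28.3 CPM (0.05 ± 0.06, adjusted p = 0.461). Of 39 ATF6 and XBP1 targets, which serve folding and degradation in the endoplasmic reticulum, 30 rose and 3 fell (4 lower when adjusted over the list alone; median 0.46, camera adjusted p = 9.5e-06; adjusted p = 0.678 with an estimated correlation). HSPA5, the reticulum chaperone BiP, rose from 418 ± 29.7 to 1365 ± 48.4 CPM (1.71 ± 0.07). HERPUD1, a component of reticulum-associated degradation, rose from 62.9 ± 4.03 to 196 ± 6.09 CPM, and SEC24D, a coat protein of export vesicles, from 26.5 ± 1.01 to 80.9 ± 0.01 CPM. ERN1, which encodes the stress sensor IRE1, rose from 15.7 ± 0.12 to 46.8 ± 1.59 CPM (1.58 ± 0.06). Of 20 cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, 18 rose and 1 fell (median 0.50, camera adjusted p = 4.9e-05; adjusted p = 0.678 with an estimated correlation). WARS1 rose by 1.71 ± 0.06 and GARS1 by 1.30 ± 0.06.

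IRE1 activates the transcription factor XBP1 by removing a 26-base intron from its messenger RNA, and the deposited transcript estimates separate the forms. XBP1 (hg38 chromosome 22, 28794555 to 28800597) rose as a gene by 0.59 ± 0.06 on the log2 scale (edgeR adjusted p = 1.1e-07). The transcripts lacking the intron held 9.37% ± 1.49 (SD, n = 2) of the gene's estimated reads with DMSO and 54.6% ± 0.14 (SD, n = 2) with MS1943. In abundance, the spliced form went from 18.2 ± 2.63 to 126 ± 6.29 TPM, Salmon's abundance scaled for transcript length, and the unspliced form from 135 ± 7.17 to 92.9 ± 0.81 TPM. The 45.2 percentage point difference exceeds the spread of either pair. The exact permutation test set beforehand for the share cannot give a p below 0.333 with 2 against 2 libraries, so it could not have called any difference. With the reads of each form as a row of the edgeR test, added after the data were seen, the spliced form rose by 3.13 ± 0.10 on the log2 scale (adjusted p = 4.0e-15) and the unspliced form fell by 0.40 ± 0.06 (adjusted p = 7.8e-06). The spliced and unspliced transcripts overlap over most of their length, and the error of assigning reads between them is not in the files or in these p-values.

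**Figure D2:**
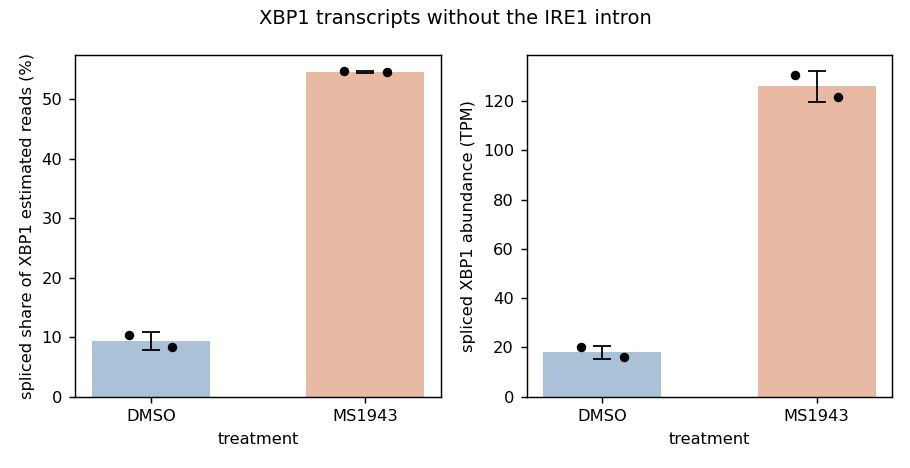
Spliced XBP1 as a percentage of the gene's estimated reads (left) and in TPM (right) for DMSO and MS1943; bars are means, error bars SD of n = 2, points libraries. The share was 9.37% with DMSO and 54.6% with MS1943.

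Cytosolic chaperones and protein disposal genes rose as well. Of 23 heat shock genes, 20 rose and 1 fell (median 0.59, camera adjusted p = 1.8e-06; adjusted p = 0.678 with an estimated correlation). HSPA1A rose 9.77-fold (3.29 ± 0.07, edgeR adjusted p = 2.0e-17) and its near-identical copy HSPA1B 7.75-fold, a split between copies that is uncertain. The co-chaperone genes DNAJB1 (1.90 ± 0.06) and BAG3 (1.41 ± 0.06) rose too. The 31 listed proteasome genes rose by a median of 0.93 (camera adjusted p = 1.6e-11, and adjusted p = 0.678 with an estimated correlation). That list leaves out the immunoproteasome genes PSMB9 (-1.02 ± 0.07) and PSMB8 (-0.47 ± 0.06, singled out after its values were seen). Both were tested on the MHC class I list and fell. The ATPase subunit gene PSMC4 rose from 164 ± 8.07 to 635 ± 11.5 CPM (1.96 ± 0.06), and the deubiquitinase subunit gene PSMD14, from 127 ± 4.23 to 348 ± 12.5 CPM (1.46 ± 0.06). Among 23 autophagy genes, 20 rose and 1 fell (median 0.53, camera adjusted p = 3.7e-06; adjusted p = 0.678 with an estimated correlation). SQSTM1, the cargo receptor p62, rose from 383 ± 1.17 to 1771 ± 71.7 CPM (2.21 ± 0.06). GABARAPL1 rose by 1.77 ± 0.06 and MAP1LC3B by 1.44 ± 0.05, both encoding autophagosome membrane proteins. Of 24 lysosomal genes, 13 rose and 4 fell (median 0.15, camera adjusted p = 0.0258; adjusted p = 0.678 with an estimated correlation). GLA, the alpha-galactosidase gene, rose by 1.93 ± 0.06 and the cholesterol transporter gene NPC1 by 1.11 ± 0.06. The lysosomal list call also ended with total-read scaling (adjusted p = 0.110) and without DMSO replicate 2 (adjusted p = 0.0804).

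Of 24 NRF2 targets, which serve the response to oxidants, 16 rose and 7 fell (median 0.51, camera adjusted p = 0.0054; adjusted p = 0.678 with an estimated correlation). HMOX1, which encodes heme oxygenase 1, rose from 18.9 ± 0.07 to 157 ± 5.19 CPM (3.06 ± 0.06, edgeR adjusted p = 5.8e-18). OSGIN1 (2.37 ± 0.06), the sulfiredoxin gene SRXN1 (2.20 ± 0.06) and the cystine transporter gene SLC7A11 (2.19 ± 0.06) rose. NQO1, a quinone reductase gene singled out after its values were seen, fell from 192 ± 14.5 to 144 ± 1.46 CPM (-0.42 ± 0.06). Of 18 hypoxia-inducible genes, 13 rose and 0 fell (median 0.46, camera adjusted p = 2.1e-04; adjusted p = 0.678 with an estimated correlation). NDRG1 (2.47 ± 0.08) and the prolyl hydroxylase gene P4HA2 (1.63 ± 0.06) rose, and the angiogenic factor gene VEGFA rose from 111 ± 5.27 to 276 ± 12.5 CPM. Of 18 glycolysis genes, 10 rose and 4 fell (11 higher when adjusted over the list alone; camera adjusted p = 0.0804, fry 0.0432). The hexokinase gene HK2 (0.82 ± 0.06) and the glucose transporter gene SLC2A1 (0.78 ± 0.06) were among those that rose. The metallothionein and zinc exporter list had 5 tested genes, of which 1 rose, SLC30A1 (0.71 ± 0.07), and 3 fell (4 when adjusted over the list alone), including MT2A (-0.71 ± 0.08), with camera adjusted p = 0.268.

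Genes of the dividing cell fell. The 39 G2 and mitosis genes had a median log2 fold change of -1.08 (camera adjusted p = 7.4e-15; adjusted p = 0.678 with an estimated correlation). KIF20A fell by 2.17 ± 0.06 (edgeR adjusted p = 2.1e-16). The cyclin A gene CCNA2 fell from 119 ± 3.72 to 38.3 ± 0.59 CPM, the survivin gene BIRC5 from 208 ± 9.65 to 70.4 ± 0.65 CPM and the kinetochore gene CENPF from 280 ± 13.3 to 101 ± 5.25 CPM. Of 42 DNA replication and S-phase genes, 38 fell, 1 rose (GINS3, 0.48 ± 0.07, singled out after its values were seen) and 3 did not pass, with median -0.65 (camera adjusted p = 1.5e-10; adjusted p = 0.678 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell from 321 ± 4.19 to 106 ± 1.71 CPM (-1.60 ± 0.06). TK1 (-1.43 ± 0.06) and UHRF1 (-1.41 ± 0.06) also fell. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose from 17.2 ± 0.38 to 106 ± 4.41 CPM (2.63 ± 0.06, adjusted p = 5.1e-17). The p53 targets, CDKN1A among them, went both ways: of 21 tested, 7 rose, including PHLDA3 (1.71 ± 0.06) and GDF15 (2.36 ± 0.14), and 11 fell, including CCNG1 (-1.16 ± 0.06). The p53 list had a median of -0.25 and a mean of 0.14, opposite in sign, and was not called (camera adjusted p = 0.655). Among 19 BCL2 family and death receptor genes, 9 rose and 7 fell (camera adjusted p = 0.567). The pro-apoptotic HRK (1.74 ± 0.09) and PMAIP1 (1.33 ± 0.08) and the death receptor gene TNFRSF10A (1.22 ± 0.07) rose, and the pro-apoptotic BMF fell (-1.78 ± 0.09).

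Of 29 interferon-stimulated genes, 28 rose, 0 fell and USP18, which encodes an ISG15-removing protease and was singled out after its values were seen, did not pass (-0.09 ± 0.07, edgeR adjusted p = 0.283). The median log2 fold change was 1.29 (camera adjusted p = 4.2e-11; adjusted p = 0.424 with an estimated correlation). IFI44L rose from 0.66 ± 0.10 to 18.6 ± 0.79 CPM (4.80 ± 0.13). IRF9 (2.12 ± 0.07) and IRF7 (1.75 ± 0.06), transcription factors of the interferon response, rose with MX1 (2.71 ± 0.06). MHC class I presentation genes were mixed, with 5 of 12 higher, 4 lower and camera adjusted p = 0.767. NLRC5, the transactivator of these genes, rose (1.06 ± 0.06) and so did HLA-C (0.77 ± 0.05), while the immunoproteasome subunit gene PSMB9 (-1.02 ± 0.07) and the tapasin gene TAPBP (-0.61 ± 0.06) fell. Of 17 tested NF-kB and inflammatory cytokine genes, 7 rose and 8 fell, with median 0.04 and mean -0.03, opposite in sign, and camera adjusted p = 0.877. LIF, a cytokine of the interleukin-6 family, rose from 22.6 ± 0.35 to 74.2 ± 4.74 CPM (1.71 ± 0.06). IER3 (1.39 ± 0.07) and ICAM1 (0.53 ± 0.06) rose as well, and the inhibitor gene NFKBIA fell (-0.58 ± 0.06).

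Of 15 basal epithelial markers, 10 rose and 3 fell (median 1.57, camera adjusted p = 0.0054; adjusted p = 0.678 with an estimated correlation). KRT16, a keratin gene of stressed and wounded epithelium, rose from 81.3 ± 1.13 to 1045 ± 64.1 CPM (3.69 ± 0.07). Of the same kind, KRT6A rose from 1.26 ± 0.02 to 113 ± 19.7 CPM (6.48 ± 0.12) and KRT6B from 68.4 ± 0.83 to 849 ± 130 CPM (3.63 ± 0.09), with an uncertain split of reads among the KRT6 copies. Luminal markers were not called as a list (15 tested, 3 higher, 9 lower, camera adjusted p = 0.207). The receptor tyrosine kinase gene KIT fell from 63.7 ± 2.57 to 16.1 ± 1.09 CPM (-1.98 ± 0.07). MUC1 (-1.51 ± 0.07), KRT8 (-0.66 ± 0.06) and FOXA1 (-0.66 ± 0.07) fell. Mesenchymal markers had 6 of 13 tested genes higher and 1 lower (camera adjusted p = 0.299). VIM, the intermediate filament vimentin, rose from 22.5 ± 1.23 to 109 ± 12.7 CPM (2.27 ± 0.07). The integrin gene ITGA5 (2.57 ± 0.10) and TGFBI (1.27 ± 0.11) rose, and the fibronectin gene FN1 fell (-1.18 ± 0.09). Of 22 immediate-early and MAPK feedback genes, 17 rose and 2 fell (median 0.71, camera adjusted p = 2.1e-04; adjusted p = 0.678 with an estimated correlation). FOSL1, a subunit of the AP-1 transcription factor, rose from 4.37 ± 0.45 to 118 ± 1.72 CPM (4.74 ± 0.07, edgeR adjusted p = 4.2e-19). Its partner gene JUN rose from 52.9 ± 3.42 to 259 ± 13.0 CPM, with PHLDA1 (2.66 ± 0.06) and ETV5 (2.07 ± 0.06). YAP and TEAD targets split 3 higher and 4 lower of 9, with median 0.10, mean 0.05 and a test pointing down (camera adjusted p = 0.946). ANKRD1 rose (1.40 ± 0.11) and CCN1 fell (-0.56 ± 0.06).

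All 13 mitochondrially encoded respiratory chain genes rose (median 0.90, camera adjusted p = 5.6e-05; adjusted p = 0.678 with an estimated correlation), beside the higher mitochondrial read share given above. MT-ND5 rose from 1127 ± 62.6 to 2727 ± 295 CPM (1.27 ± 0.08), MT-ND4 by 1.26 ± 0.08 and MT-ND6 by 1.38 ± 0.08. These genes abut or overlap on both strands and have nuclear copies, so the split of reads among them is uncertain. Nuclear-encoded subunits of the same chain went the other way, with 33 of 58 lower and 5 higher (median -0.21, camera adjusted p = 0.0059; adjusted p = 0.678 with an estimated correlation, and 0.0583 with fry). NDUFA2 (-0.71 ± 0.06) and ATP5F1E (-0.71 ± 0.06) fell. Of 74 cytosolic ribosomal protein genes, which have many processed pseudogenes, 24 rose and 13 fell (22 higher when adjusted over the list alone). RPL37 rose by 0.54 ± 0.06, and RPL7A fell (-0.34 ± 0.06). Their median of 0.05 turned to -0.07 with total-read scaling, and the list was not called (camera adjusted p = 0.412). Cholesterol synthesis genes were 7 higher and 11 lower of 25 (8 higher when adjusted over the list alone; camera adjusted p = 0.394), with TM7SF2 lower (-1.44 ± 0.07) and STARD4 higher (0.91 ± 0.06). Fatty acid synthesis genes were 4 higher and 8 lower of 15 (camera adjusted p = 0.502), with SREBF1 (-0.57 ± 0.06) and ACLY (-0.53 ± 0.06) lower.

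**Figure D3:**
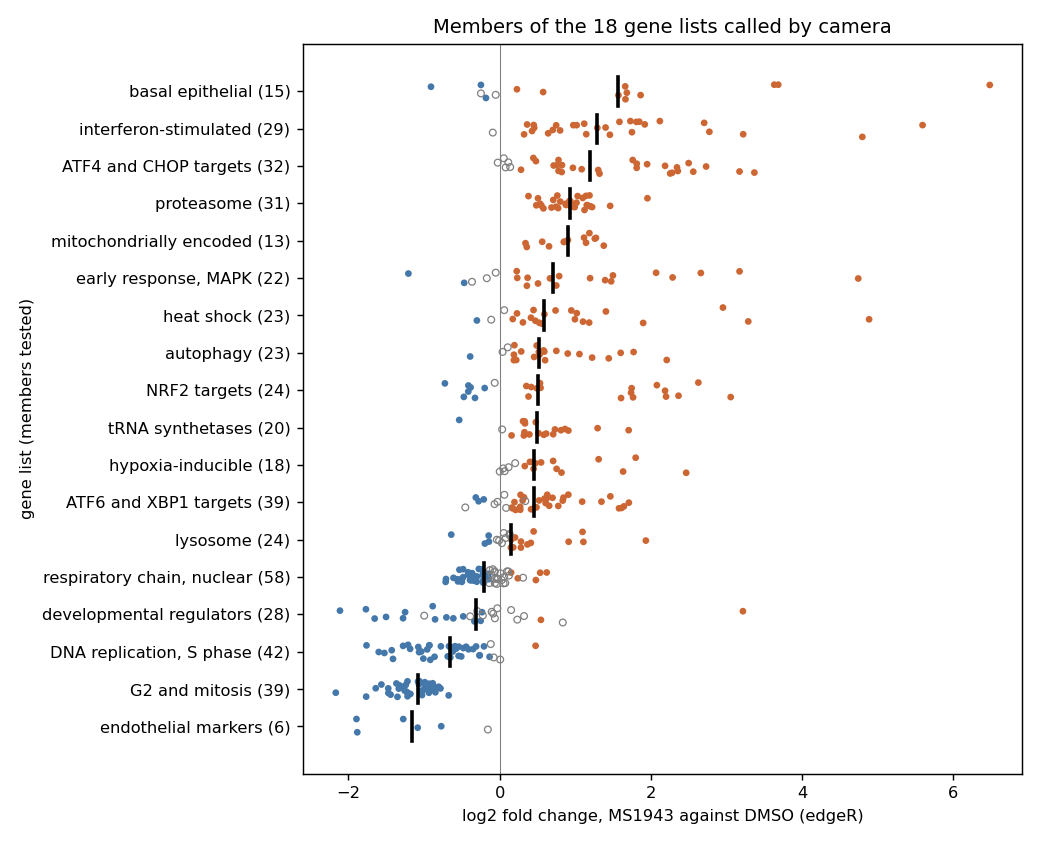
log2 fold change (MS1943 over DMSO) of each tested member of the 18 gene lists called by camera; filled points passed the gene test (orange higher, blue lower) and open grey points did not. Black bars are list medians, and the number of tested members is in brackets. Medians run from -1.16 (endothelial markers) to 1.57 (basal epithelial markers), and no list was called with an estimated correlation.

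Among protein-coding genes with an average log2 CPM of at least 2, the 12 largest rises included that of HKDC1, a hexokinase family gene, from 0.14 ± 0.12 to 14.6 ± 1.54 CPM (6.59 ± 0.22). It was followed by KRT6A (6.48 ± 0.12), ZNF365 (6.28 ± 0.19) and the keratin gene KRT75 (6.24 ± 0.13). IFI27, an interferon-induced gene, rose by 5.59 ± 0.21, CD68 by 5.03 ± 0.11 and the receptor phosphatase gene PTPRH by 5.01 ± 0.14. MAP1B, a microtubule-associated protein gene, rose from 2.22 ± 0.25 to 84.5 ± 0.19 CPM and OLFML3 from 3.51 ± 0.15 to 112 ± 2.39 CPM. Also among them were BHMT2, a methyltransferase gene (4.90 ± 0.12), and the mucin glycosyltransferase gene GCNT3 (4.81 ± 0.16). The largest fall was that of STAC2, from 27.9 ± 1.56 to 0.81 ± 0.31 CPM (-5.05 ± 0.13). IGFBP5, a binding protein of insulin-like growth factors, fell from 162 ± 4.31 to 11.9 ± 0.86 CPM (-3.76 ± 0.07). SOSTDC1, a secreted BMP and WNT antagonist, fell from 109 ± 4.58 to 10.6 ± 0.92 CPM, and ATP6V1B1, a proton pump subunit, from 231 ± 1.17 to 27.6 ± 2.00 CPM. Other falls included those of UPK3B (-3.50 ± 0.11), the endothelin gene EDN2 (-3.37 ± 0.16), PLEKHS1 (-3.20 ± 0.11), the mucin gene MUC5B (-2.96 ± 0.17), NDRG2 (-2.86 ± 0.13), PSCA (-2.80 ± 0.16) and the ceruloplasmin gene CP (-2.78 ± 0.09). The edgeR adjusted p of all 24 genes with the 12 largest rises and 12 largest falls lay between 3.1e-19 and 2.0e-11.

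Markers of cell types other than the line were read as a check. Of 10 leukocyte markers, 4 could be tested, too few for a list test. CD68 rose from 0.95 ± 0.18 to 30.8 ± 1.64 CPM and CSF1R, the receptor of macrophage colony-stimulating factor, from 1.98 ± 0.11 to 35.7 ± 1.23 CPM (4.17 ± 0.09). CD14 fell from 155 ± 11.4 to 86.8 ± 0.82 CPM and ITGAM from 0.25 ± 0.05 to 0.07 ± 0.03 CPM. The ITGAM call ended without DMSO replicate 2 (adjusted p = 0.0961), without MS1943 replicate 1 (adjusted p = 0.168), with DESeq2 (adjusted p = 0.147) and with the length offset (adjusted p = 0.0806). PTPRC, the pan-leukocyte marker CD45, had 4 and 4 reads with DMSO and 10 and 2 with MS1943. Of 6 tested fibroblast markers, 2 rose and 1 fell (camera adjusted p = 0.556). COL1A1 rose from 20.9 ± 0.30 to 29.6 ± 2.40 CPM, and PDGFRA fell from 3.42 ± 0.03 to 0.76 ± 0.14 CPM. PDGFRB rose from 0.06 ± 0.04 to 0.25 ± 0.07 CPM, a call that ended without DMSO replicate 1 (adjusted p = 0.0765), without MS1943 replicate 1 (adjusted p = 0.174), with DESeq2 (adjusted p = 0.1001) and with the length offset (adjusted p = 0.449). Of 6 tested endothelial markers, all at low levels, 5 fell (median -1.16, camera adjusted p = 0.0095; adjusted p = 0.678 with an estimated correlation). KDR fell from 4.51 ± 0.04 to 1.87 ± 0.11 CPM and ESAM from 4.35 ± 0.37 to 2.06 ± 0.15 CPM.

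Of 36 lists, 35 had the 5 tested members that camera required, and 18 were called, 13 up and 5 down. With an estimated correlation no list was called (lowest adjusted p = 0.424; 2 lists at an unadjusted p under 0.05), while fry called 24. Counts of members adjusted over the list alone equalled those over all genes except where given.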

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

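The analysis without mitochondrially encoded genes and the edgeR test of the XBP1 forms were chosen after the data were seen. Most named genes were chosen in the main test for a small adjusted p or a large change, which favours stable calls. Across alternatives, the 171 named genes that could be tested kept their direction, with few calls gained or lost. Of these, 4 were lost with the transcript length offset (ESR1, ITGAM, PDGFRB and CDH5), 3 with DESeq2 (ITGAM, PDGFRB and PECAM1), and EED was gained with total-read scaling. Leaving out 1 library ended 3 calls without DMSO replicate 1, 1 without DMSO replicate 2 and 4 without MS1943 replicate 1. Over these fits the counts ran from 4986 to 5730 higher and 5130 to 5624 lower, at least 2-fold from 1355 to 1606 higher and 1440 to 1499 lower, and 17 to 20 lists. The lone library of a group is then assumed to vary like the other group. Over all genes more calls were lost than among the named genes. DESeq2 called 9392 genes, of which 9367 were among the 11488 of the edgeR test (81.5% of them), all in the same direction. The transcript length offset called 9958 genes, of which 9621 were among the 11488 (83.7% of them), 9618 in the same direction. The HOX list was gained with no low-count filter (adjusted p = 0.0256), with the length offset (0.0311) and without MS1943 replicate 2 (0.0149), and the glycolysis list with no low-count filter (0.0457), with 10 reads in every library (0.0458) and without MS1943 replicate 2 (0.0323). With protein-coding genes only, 1016 genes were lower at least 2-fold, since 14501 in place of 19358 genes were tested. With an estimated correlation 0 lists were called, and with fry, 24. Lost with fry were the developmental regulators (0.0514) and the nuclear respiratory chain (0.0583), and gained were the EZH2-repressed (0.0332), HOX (0.0132), NF-kB (0.0187), apoptosis (0.00716), glycolysis (0.0432), luminal (0.00686) and mesenchymal (0.0272) lists. The fry test also pointed the p53 list up (adjusted p = 0.0213), the sign of its mean (0.14) and not of its median (-0.25). No further cause was tested. Without the mitochondrially encoded genes 5789 genes were higher and 5680 lower, with 17 lists called. The list lost was that of the removed genes, and the other 34 lists kept their result. The spliced XBP1 difference was 45.2 points from reads and 45.7 points from TPM. The 47564377 reads of MS1943 replicate 2 limit what can be read at low CPM. No paired analysis was possible because the letters in the sample titles, which could mark pairs or pools, are not explained by any label.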

Other observations

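The genes of this and the next paragraph were singled out by eye after their values were seen, and no enrichment of any group was tested. The tests on leukocytes, on neighbouring genes and on keratinocytes were rewritten after their results were seen. The tests of short transcripts, keratin copies, interferon transcripts and silent genes were set beforehand. SERPINB5, the serpin maspin, rose from 3.96 ± 0.08 to 72.3 ± 0.12 CPM (log2 fold change 4.19 ± 0.07, edgeR adjusted p = 1.2e-18, n = 2 per group), PADI1, a peptidylarginine deiminase, from 1.82 ± 0.27 to 30.6 ± 0.31 CPM (4.06 ± 0.10), and DSG3, a desmosomal cadherin, from 0.17 ± 0.07 to 7.88 ± 1.01 CPM (5.58 ± 0.22). ANXA1, the annexin, rose from 78.6 ± 2.64 to 632 ± 1.85 CPM, the interleukin-1 receptor antagonist gene IL1RN from 1.96 ± 0.08 to 26.4 ± 1.51 CPM and S100P, a calcium-binding protein gene, from 9.16 ± 0.43 to 107 ± 3.24 CPM. UPP1, which encodes uridine phosphorylase, rose from 74.4 ± 2.66 to 1039 ± 12.2 CPM (3.80 ± 0.07), and the long non-coding RNA UCA1 from 17.2 ± 1.03 to 182 ± 2.55 CPM (3.40 ± 0.06). The growth arrest gene GADD45A rose from 44.9 ± 2.39 to 336 ± 27.4 CPM and MYC from 94.7 ± 2.32 to 268 ± 4.55 CPM.

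C3, the central complement component, fell from 347 ± 13.3 to 69.6 ± 2.99 CPM (-2.32 ± 0.06, edgeR adjusted p = 2.4e-16, n = 2 per group). The serum amyloid genes SAA1 (-2.58 ± 0.11) and SAA2 (-2.60 ± 0.13), whose reads are hard to separate, the calprotectin gene S100A8 (-2.23 ± 0.09) and CRISP3 (-2.70 ± 0.11) fell, but SERPINA3, which encodes antichymotrypsin, rose from 20.7 ± 0.19 to 260 ± 4.53 CPM (3.65 ± 0.06) and the lipocalin gene LCN2 by 0.48 ± 0.06. CD24, a surface glycoprotein gene, fell from 2128 ± 134 to 364 ± 3.16 CPM (-2.55 ± 0.07). CXCL10, an interferon-induced chemokine gene on the EZH2-repressed list, fell from 0.41 ± 0.07 to 0.07 ± 0.02 CPM (-2.47 ± 0.52), a low level, while 28 of 29 interferon-stimulated genes rose.

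CD68 and CSF1R, macrophage markers, rose to 30.8 and 35.7 CPM with MS1943. Leukocytes in these libraries would bring PTPRC, LYZ, TYROBP and other abundant transcripts, but the largest gain among PTPRC, LYZ, CD14, TYROBP and LAPTM5 was 0.134% of that of CD68. A first version of this test, which did not subtract the DMSO level, gave 281% through CD14, at 155 CPM with DMSO. Reads from neighbouring genes would give no larger a fold change than their source if the share of misassigned reads stayed fixed. CD68 and CSF1R exceeded the most increased gene within 10 kb by at least 2.04 on the log2 scale. The first version of that test looked only at the neighbours, of which SOX15 rose by 2.23. The comparison cannot exclude a share that grew with treatment, since some neighbours were abundant. With DMSO and MS1943, EIF4A1 near CD68 stood at 431 and 403 CPM and HMGXB3 near CSF1R at 69.3 and 101 CPM. Such a growing share and expression by the cancer cells themselves both stay open as hypotheses, and the protein was not measured.

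Mitochondrially encoded transcripts rose while 33 of 58 nuclear respiratory chain genes fell. A bias towards short transcripts would raise nuclear genes of like length. Abundant nuclear protein-coding genes with a Salmon effective length of 200 to 1900 bases, 1624 in number, had a median log2 fold change of 0.0064 (quartiles -0.28 and 0.30). The median of all tested genes was -0.00998. Effective length is not the annotated transcript length, and longer genes were not compared separately. The result argues against a general bias towards genes of short effective length as the cause. A change in mitochondrial RNA content or in its polyadenylation, which could alter poly(A) capture, was not tested.

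Keratin genes KRT6A, KRT6B and KRT16 rose 12.4-fold or more. A shift of reads between copies would leave their sum in place, but the summed CPM of 8 keratin genes rose by 2.06 on the log2 scale. KRT5, from 1068 to 3888 CPM, and KRT17, from 324 to 1025 CPM, carry much of that sum, so it says little on the KRT6 copies. Each of the 8 genes nevertheless rose in mean CPM, KRT6C from 0.01 to 2.59, where a shift among them alone would make some fall. Keratinocytes mixed into the MS1943 libraries would raise KRT14 with its partner KRT5; KRT14 gained 1.05% of the CPM that KRT5 gained, TP63 stood at 0.44 and 0.37 CPM, DSC3 at 98.6 and 98.1, KRT15 at 108 and 95.3 and KRT1 at 0.00666 and 0. Other keratinocyte genes rose as mixing would have it: DSG3 from 0.17 to 7.88 CPM, SFN from 201 to 402, COL17A1 from 0.09 to 0.37, KRT10 from 24.2 to 38.9, DSP from 793 to 1113 and PERP from 395 to 527. A first version, which compared the KRT5 and KRT14 gain with that of KRT6A, KRT6B and KRT16, gave 154% and was met through KRT5 alone, and a keratin response of the treated cells may account for the pattern but remains a hypothesis found and tested on the same data.

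Interferon transcripts made by the treated cells may underlie the higher interferon-stimulated genes. Of 22 type I, II and III interferon genes, 0 had 10 or more reads in both MS1943 libraries and more than in both DMSO libraries. IFNL1 had 11 and 3 reads with MS1943 and 5 and 6 with DMSO, IFNL3 had 5 and 7 against 1 and 0, and IFNB1 had 2 and 1 against 0 and 0. So few reads decide nothing, and the source of the response cannot be told apart from these data.

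Genes silent in 1 treatment were taken as those under 0.1 CPM in both of its libraries and at 1 CPM or more in both of the other. All 28 such genes were silent with DMSO (100%, exact Clopper-Pearson 95% interval 87.7% to 100%) and 0 with MS1943, among them MAGEC2, SERPINB3, APOBEC3A, KRT34 and TIMP4. The interval, and the Fisher test below, treat genes as independent and do not measure the spread between libraries. KRT6C and KRT16P2 are also among the 28, and as keratin copies may hold reads of KRT6A, KRT6B or KRT16. Silence with DMSO alone is what would be seen if silenced genes were released by MS1943 more often than active genes were shut off. Genes detected in both treatments leaned the same way, however, with 64 at least 10-fold higher and 11 at least 10-fold lower (85.3% higher; two-sided Fisher's exact p = 0.0329 between these classes, a test added after the counts were seen), so the lean towards rises is not confined to silent genes.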
